A study of Mus musculus with 36 samples.

How the data were processed

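Total RNA from individual mouse spleens was extracted with Trizol, labelled with biotin and hybridised to Affymetrix mouse arrays by the manufacturer's protocol, per the labels. Each array stands for 1 mouse, and the groups and replicate numbers were taken from the sample titles. The design text counts the animals in a way that differs from its own group sizes, and the 18 arthritic and 18 non-arthritic arrays of the labels were used here. The deposited values are microarray intensity on a linear scale, made with MAS5 per the submitters' processing notes, with the version not given in the sources used here. Every array had a trimmed mean of 499.9 after 2% of the probe sets were taken off each end, so each array had been scaled by 1 factor, and values ran from 0.103 to 67960.

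Values were analysed as log2(value + 16) with no further normalization between arrays. The 64 control probe sets of the manufacturer were left out of all tests on genes, and probe sets whose mean over the 36 arrays lay below the 40th percentile (a mean log2 of 6.49) were left out as low, which left 27022 of 45037. A log2 difference on this scale understates the change of dim probe sets. Genes were named from the platform annotation, in which 34945 probe sets name 1 gene and 932 several, while 9160 are not listed there and stay unnamed here. Of the former, 34754 matched a gene of the reference table (assembly GRCm38.p6) by gene identifier. A gene was represented by its probe set with the highest mean over all arrays, which gave 12427 genes among the tested probe sets. Of the listed genes of all lists, 55 had no probe set.

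Groups were compared per probe set with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a trend in the variance prior, two-sided, Benjamini-Hochberg adjustment over all tested probe sets, threshold 0.05). Spread was compared with the same functions on absolute deviations from the group median. List scores were the mean of gene-centred log2 values per mouse, for 27 lists with at least 5 tested members, and were compared by two-sided permutation tests with 100000 label permutations, adjusted over the lists. Camera and fry were run as alternatives. Whole profiles were compared through 1 minus Pearson correlation over the 1000 most variable probe sets, by pseudo-F, by the distance to group centroids, and by average linkage clustering with silhouettes set against 1000 simulated single populations. Correlations of list scores were computed over 28 pairs of 8 lists in each group, without genes that are in more than 1 list, each with a permutation p and adjusted per group. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0 and matplotlib 3.10.9 were used.

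The groups, tests, lists, main settings and first set of other settings were chosen before the data were examined. So was the rule for named genes. Of genes past the threshold it takes the 12 with the largest positive and the 12 with the largest negative difference, and, if fewer than 10 pass, also the 5 highest and 5 lowest by moderated t, given as values. For the spread test it takes the 6 largest rises and the 6 largest falls past the threshold. From each list described it takes up to 4 members with the smallest unadjusted p, or by the spread test where the text is on spread, and always Il1rn and the sex-linked genes. Probe sets that passed but do not represent a gene, Ebf1, Cd3e, H2-Ea and H2-Eb1 of the lists, the genes named for spike-in batches, and the genes with a high and a low set of mice were named after their values were seen.

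Some choices were made after the data were seen. Spike-in batches are Ward clusters of the hybridisation control probe sets, with the number of clusters set at 3 after the first expression component had been seen, and other numbers, average linkage and 2 principal components of the controls were run beside it. An array was left out for a high actin 3 prime to 5 prime ratio only by a limit applied to all 36 arrays, which 1 array exceeded. An earlier run without arthritic replicates 14 and 18 is not reported as a result, because replicate 18 had been picked for its expression profile. In it the 738 probe sets of batch B became 0, as they also do when replicate 18 alone is left out in turn.

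Simulated arrays for the limma tests had the real means and the residual SDs left by group and batch, with independent noise. Without a batch effect, limma recovered 68 of 100 probe sets changed by 0.5 log2 and 97 of 100 changed by 1 among 27022. With a simulated batch effect it recovered 59 and 94 with no block, as in the main test, and 71 and 93 with the batch as a block. The spread test recovered 3 of 100 probe sets whose SD was multiplied by 2 and 32 of 100 at 3. The list test recovered 2, 56 and 96 of 100 lists shifted by 0.5, 1 and 1.5 SD. Its simulated scores were independent between lists and had the SD of each list over all mice. The rule for high and low sets made 0 calls among 12417 genes drawn from 1 normal population each, with the mean and SD of the gene over all mice. No 2 arrays were identical, and the correlation of 2 arrays ran from 0.886 to 0.974. Pixel-level array files were not analysed here, so detection calls and scan dates were not used.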

Results

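Spleen RNA was profiled in 36 mice, 18 that had developed arthritis and 18 that had not, on 1 Affymetrix mouse expression array per mouse. The animals were 4 months old and came from the F2 generation of a cross. The series title describes the arthritic mice as lacking the interleukin 1 receptor antagonist, the secreted inhibitor that competes with interleukin 1 for its receptor and is encoded by Il1rn. The labels give no genotype, sex, arthritis score or processing date for any mouse, and the stated purpose was to look for subpopulations among the arthritic animals. The table holds 45101 probe sets, and the median intensity per array lay between 110.6 and 183.2. The number of arrays limits the precision.

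Il1rn gave a low signal in both groups, with mean log2 levels of 6.48 ± 0.65 (SD, n = 18) in arthritic and 6.52 ± 0.55 (SD, n = 18) in non-arthritic spleens, a difference of -0.04 (SE 0.20, limma adjusted p = 0.941). Whether its probe set lies in the deleted part of the gene is not given in the sources used here, so this level does not check the labels. The Y-linked genes were well measured in both groups: Eif2s3y at 10.77 and 10.68, Kdm5d at 9.05 and 9.01, and Uty at 8.62 and 8.46 on the log2 scale. Xist, the RNA that silences 1 X chromosome in females, was at 7.23 in arthritic and 7.49 in non-arthritic spleens.

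The first comparison asked which transcripts differed between arthritic and non-arthritic spleens. Genes that rose in the arthritic group included Ptpn22, a tyrosine phosphatase that restrains antigen receptor signalling in lymphocytes, which was higher by 0.44 (SE 0.09) on the log2 scale, a 1.36-fold difference. Il12a, which encodes a subunit of the cytokine interleukin 12, rose by 0.35 (SE 0.07), and Bid, a pro-apoptotic member of the Bcl-2 family, by 0.34 (SE 0.07). Snx5, a sorting protein of endosomes, rose by 0.37 (SE 0.07), Arpc5l, a subunit of the actin-nucleating Arp complex, by 0.33 (SE 0.07), and Smpdl3a, a phosphodiesterase related to acid sphingomyelinase, by 0.29 (SE 0.06). Among further probe sets, which are not the ones chosen to represent their gene, 1 probe set of the semaphorin receptor Plxnc1 showed the largest rise, 0.72 (SE 0.13), a 1.65-fold difference.

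Gm2a, whose product helps degrade gangliosides in lysosomes, rose by 0.57 (SE 0.12) on 1 probe set, Slc35a3, a nucleotide sugar transporter of the Golgi, by 0.48 (SE 0.10), Usp3, a deubiquitinase, by 0.45 (SE 0.09), and Wdr43, a nucleolar protein, by 0.26 (SE 0.05). The 4 other probe sets of Plxnc1 and the 3 others of Usp3 pointed the same way without passing. Of the 4 other probe sets of Snx5, 2 pointed the same way, and of the 2 others of Arpc5l, 0 did. The lowest moderated t among representative probe sets belonged to Pik3r3, a regulatory subunit of a phosphoinositide kinase, with a difference of -0.35 (SE 0.07, adjusted p = 0.0531), and to the bromodomain protein Brd3 with -0.48 (SE 0.10, adjusted p = 0.0569). Cadm1, an adhesion molecule, differed by -0.28 (SE 0.06), Zfp185 by -0.73 (SE 0.16) and Id4, an inhibitor of helix-loop-helix factors, by -0.52 (SE 0.12), and these also did not pass.

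**Figure D1:**
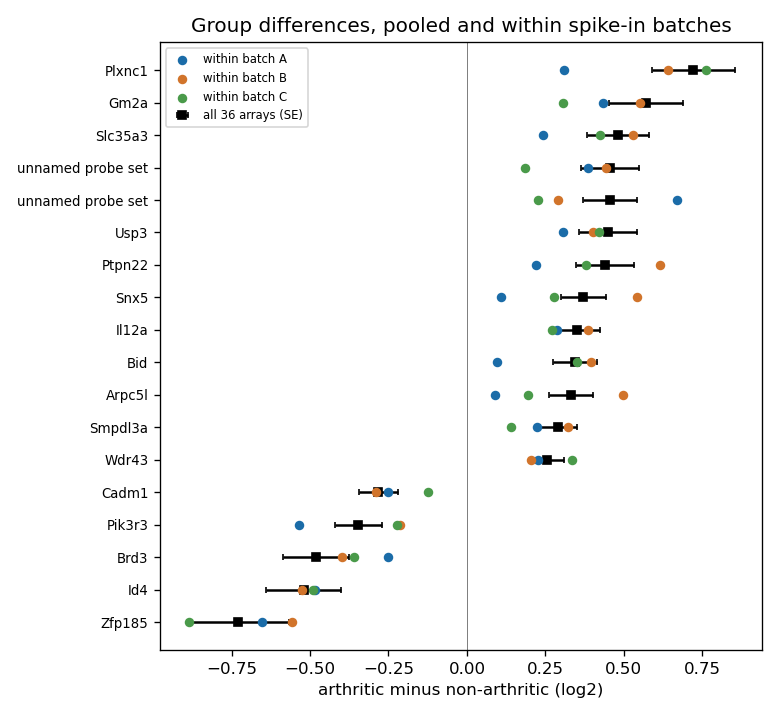
Log2 difference, arthritic minus non-arthritic, of the 13 probe sets that passed and of the 5 genes with the lowest moderated t, which did not. Black squares are all 36 arrays with the standard error, and coloured points are differences within spike-in batches A, B and C. Every one of the 13 lies above 0 in each batch, which their choice by the pooled difference favours. Plxnc1 has the largest pooled value, 0.72.

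In all, limma called 13 of the 27022 tested probe sets higher and 0 lower at the adjusted threshold of 0.05, and 4250 had an unadjusted p under 0.05. All 13 had an adjusted p of 0.0485, close to the threshold, and the Wilcoxon rank-sum test called 0, with 4155 at an unadjusted p under 0.05. The limma count was 0 without the filter or without the trend, 1 after quantile normalization and 2 with the Gapdh ratio as a covariate. It was 220 (144 higher, 76 lower) with the pancreas score and 2322 (1362 higher, 960 lower) with Xist. The count with Xist cannot be read as one adjusted for sex, since Y-linked genes were well measured in both groups. What the Xist level stands for in these mice was not tested. With batches read from the spike-in controls as a block (described below), the limma count was 0, with 3221 at an unadjusted p under 0.05, and the blocked difference was 0.77 to 0.98 of the unblocked one for the 13 probe sets (lowest adjusted p 0.0645). Within batches A, B and C the difference of Ptpn22 was 0.22, 0.61 and 0.38, that of Il12a 0.29, 0.38 and 0.27, and that of Plxnc1 0.31, 0.64 and 0.76. Within batches limma called 0 probe sets in A (3129 at an unadjusted p under 0.05), 738 in B (346 higher and 392 lower) and 0 in C (1000), and the 738 became 4, 5, 3 and 0 without arthritic replicates 14, 15, 16 and 18, 1174 and 2200 without arthritic replicates 10 and 17, and 275 to 956 without single non-arthritic arrays. Leaving out single arrays from all 36 gave between 0 and 389.

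The second comparison used 27 gene lists chosen for spleen cell types and inflammatory pathways. Genes of plasma cells and their secretory apparatus had a higher mean score in arthritic spleens, by 0.16 (arthritic 0.08 ± 0.18 and non-arthritic -0.08 ± 0.16, SD, n = 18 each), and 14 of 18 arthritic mice lay above the non-arthritic median. Of its 18 members, 15 had a positive difference and 0 passed over all genes. Adjusted over the list alone, 2 members were higher, and 6 with the spike-in batch as a block. The examples are Sdf2l1 at 0.54 (SE 0.15), Fkbp11 at 0.34 (SE 0.11), Pdia4 at 0.44 (SE 0.17) and Herpud1 at 0.24 (SE 0.10, with -0.02 in batch C), which serve protein folding and quality control in the endoplasmic reticulum. Jchain at -0.04 (SE 0.07), Igha at -0.06 (SE 0.13) and Mzb1 at 0.0009 (SE 0.08) did not rise. Sdc1 at 0.11 (SE 0.12), Prdm1 at 0.15 (SE 0.12) and Tnfrsf17 at 0.14 (SE 0.11) were positive. The score thus does not tell a change of plasma cells from one of folding genes. The list score did not pass over the 27 lists (permutation p = 0.00687, adjusted p = 0.0927). With the spike-in batch as a block it passed narrowly, at 0.19 with an adjusted p of 0.0481, and its within-batch differences were 0.20 in A, 0.26 in B and 0.05 in C.

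Genes of the interleukin 1 family and its signalling had a score difference of 0.12 (permutation p = 0.0046, adjusted p = 0.0927), with 15 of 18 arthritic mice above the non-arthritic median. Of 18 members 15 had a positive difference. None of them passed in limma, over all genes or adjusted over the list alone (0 members, with 5 at an unadjusted p under 0.05). Casp1, the protease that activates interleukin 1 beta, differed by 0.18 (SE 0.08, with -0.13 in batch A, 0.45 in B and 0.12 in C), the receptor-proximal kinase Irak2 by 0.16 (SE 0.07), the adaptor Myd88 by 0.15 (SE 0.06) and the inhibitory receptor Sigirr by 0.17 (SE 0.08). With the spike-in batch as a block the score difference was 0.08 (adjusted p = 0.343), and within A, B and C it was 0.01, 0.13 and 0.10.

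Interferon response genes had a score difference of 0.24 (permutation p = 0.0551, adjusted p = 0.372), with 0.53 in batch A, -0.13 in B and 0.26 in C. Of its 20 members 17 had a positive difference, 0 passed over all genes and 2 were higher adjusted over the list alone. The members with the smallest p were the signal transducer Stat2 at 0.48 (SE 0.13), the chemokine Cxcl9 at 0.51 (SE 0.15), the antiviral GTPase Mx1 at 0.44 (SE 0.17) and the nucleic acid sensor Zbp1 at 0.25 (SE 0.11). Mast cell, basophil and eosinophil genes differed by 0.21 (adjusted p = 0.385). All 11 tested members had a positive difference, and 2 were higher adjusted over the list alone: Ms4a2 at 0.58 (SE 0.18) and Fcer1a at 0.51 (SE 0.17), chains of the high-affinity IgE receptor. With the spike-in batch as a block the score difference was 0.08 (adjusted p = 0.603), with 0.36 in A, -0.10 in B and 0.05 in C, and 0 members were higher over the list alone (Ms4a2 0.46, SE 0.18, and Fcer1a 0.41, SE 0.18).

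Erythroid genes were at -0.18 (permutation p = 0.195, adjusted p = 0.526), with 22 of 23 members negative and 1 lower adjusted over the list alone, Xpo7 at -0.30 (SE 0.09), and 0 with the batch block. Ermap differed by -0.28 (SE 0.13, 0.20 in batch A) and the haem synthesis enzyme Alas2 by -0.27 (SE 0.14, 0.14 in A). The direction of the erythroid score was not shared by the batches: 0.32 in A, -0.68 in B and -0.08 in C. Cell cycle genes were at -0.16 (adjusted p = 0.522), with 26 of 27 members negative, Ccna2 at -0.32 (SE 0.15, 0.37 in batch A) and Mcm4 at -0.21 (SE 0.11, 0.28 in A), and with 0.29 in batch A, -0.52 in B and -0.11 in C. Stroma and endothelium genes were at -0.14 (adjusted p = 0.372), with 10 of 16 members negative and 6 positive (median -0.06). Lower adjusted over the list alone were 4 members: the collagen Col3a1 at -0.42 (SE 0.12), smooth muscle actin Acta2 at -0.40 (SE 0.13), and the matrix proteoglycans Dcn at -0.74 (SE 0.26) and Lum at -0.50 (SE 0.18). Among the positive members were Stab2 at 0.36 (SE 0.17) and Pecam1 at 0.13 (SE 0.07). With the batch block the score difference was -0.09 (adjusted p = 0.375), with -0.21 in A, -0.01 in B and -0.05 in C. Then 0 members were lower over the list alone, with Col3a1 at -0.29, Acta2 at -0.21, Dcn at -0.41 and Lum at -0.49.

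Single genes of further lists also stood out adjusted over the list alone, with 0 members past the threshold over all genes. These were H2-DMb2 of antigen presentation at 0.41 (SE 0.10), the costimulator Cd86 of dendritic cells at 0.22 (SE 0.07), Fcrl1 of B cells at 0.36 (SE 0.11, with -0.10 in batch A, 0.60 in B and 0.23 in C), and among osteoclast and matrix genes Acp5 at 0.26 (SE 0.07) and Mmp3 at -0.36 (SE 0.11). With the batch block 0 dendritic cell members stood out, and Cd86 was at 0.17 (SE 0.07), with 0.01 in batch A. Other lists gained members with the block: 3 red pulp macrophage genes were lower, 2 B cell genes were higher, and so was 1 gene each of germinal centres, granulocyte precursors and TNF targets. Score differences of the monocyte list were 0.16, of megakaryocytes and platelets 0.18, of class II antigen presentation 0.18, of neutrophils 0.08, of dendritic cells 0.07, of germinal centres 0.07, of acute phase and complement genes 0.07 and of regulatory and activated T cells 0.07. They were 0.06 for cytotoxic cells, 0.05 for B cells, 0.05 for red pulp macrophages, -0.01 for granulocyte precursors, -0.01 for Th17 genes, -0.06 for T cells, -0.02 for TNF and NF-kappaB targets, -0.02 for chemokines, -0.03 for osteoclast and matrix genes, -0.13 for immediate early and heat shock genes, -0.39 for adipose genes and -0.21 for pancreas acinar genes. In the class II list H2-Eb1 (0.61, SE 0.43) and H2-Ea (0.61, SE 0.47) had the largest differences, and the median over its 12 members was 0.08. These 2 genes split the mice of both groups into a high and a low set, and H2-Eb1 was at 1.83 in A, 1.03 in B and -1.26 in C. With the batch block some score signs turned, to -0.15 for red pulp macrophages, 0.05 for T cells, -0.09 for cytotoxic cells, 0.07 for granulocyte precursors and 0.01 for TNF targets. Among monocyte genes Lyz2 differed by 0.18 (SE 0.06) and Ms4a6c by 0.47 (SE 0.17), and 12 of 13 members were positive. With the block the monocyte score difference was 0.05 (adjusted p = 0.588), with 0.18 in A, -0.10 in B and 0.18 in C, and Ms4a6c was at 0.22 (SE 0.11). The B cell factor Ebf1 pointed against its list, at -0.47 (SE 0.17). The T cell receptor chain Cd3e was at -0.47 (SE 0.15), in a list of 8 positive and 11 negative members, with Cd8a at 0.30 (SE 0.12).

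**Figure D2:**
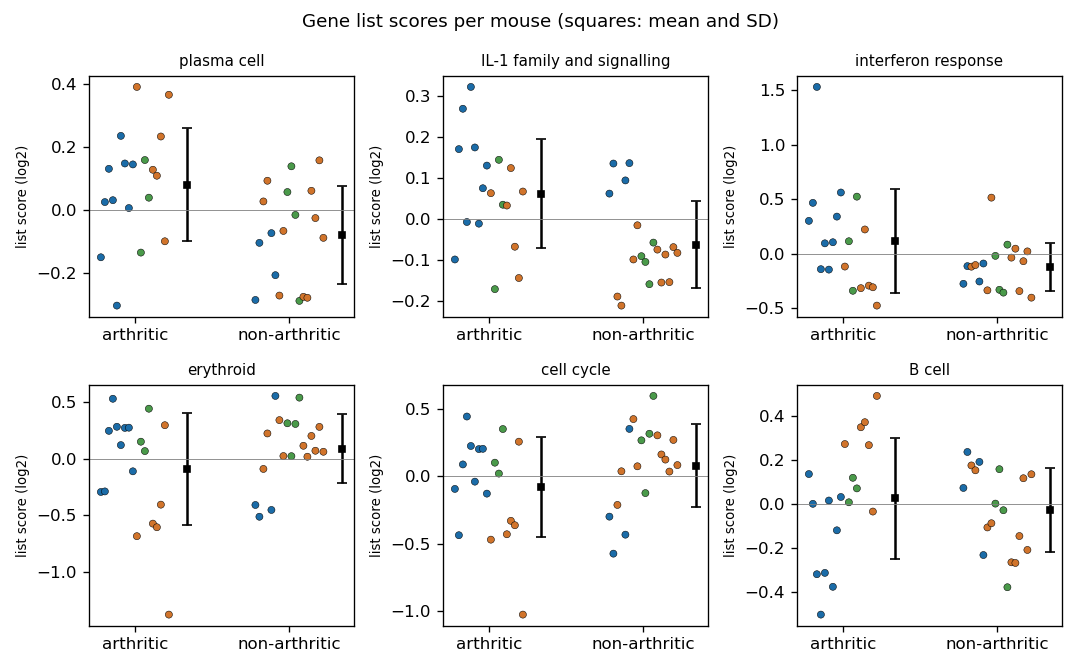
Mean log2 scores of 6 gene lists in each mouse, arthritic on the left and non-arthritic on the right, coloured by spike-in batch (blue A, orange B, green C). Black squares with bars are the group mean and SD of 18 mice. The plasma cell score differed by 0.16 and the erythroid score by -0.18, and neither passed over the 27 lists.

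Over the 27 lists, 0 passed the permutation test at the adjusted threshold, and 2 had an unadjusted p under 0.05. Camera with a preset correlation called 9 lists, among them erythroid, cell cycle, interferon, plasma cell and interleukin 1 family genes. With a correlation estimated from the data 0 of these calls held (lowest adjusted p = 0.435 with an estimated correlation). Fry, which tests whether a list's genes move on balance in 1 direction and compares the list with no other genes, called 1, the interleukin 1 family (adjusted p = 0.0455).

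The third comparison concerned the whole profile and the arthritic subpopulations that the series title names. Over the 1000 most variable probe sets, the group took 5.76% of the variation between arrays (pseudo-F 2.08, permutation p = 0.0371). With spike-in batch taken out and labels permuted within batches it took 6.05% (pseudo-F 2.19, p = 0.00314). Arthritic arrays lay on average 0.234 ± 0.052 (SD, n = 18) from their group centroid and non-arthritic arrays 0.243 ± 0.073, a difference of -0.009 (permutation p = 0.673). Hierarchical clustering parted the 18 arthritic arrays into 4 clusters with a mean silhouette of 0.255, and simulations of 1 population with the same variances gave a mean of 0.296 (p = 0.758). The largest cluster held 8 arrays, and arthritic replicates 1 and 13 each formed a cluster alone. The 18 non-arthritic arrays gave 2 clusters with 0.319 (p = 0.268). The simulations took the principal component variances of the same arrays, so a real division widens them too. A division of the arthritic arrays by spike-in batch (described below), with 8010 probe sets past the limma threshold, was not detected in this way. The clustering p thus cannot argue against subpopulations.

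A division in the added control RNAs ran through both groups. The bacterial and phage RNAs that are added to every sample as hybridisation controls parted the 36 arrays into batch A (9 arthritic and 4 non-arthritic arrays), batch B (6 and 10) and batch C (3 and 4). Batch A held arthritic replicates 1 to 9. All 18 arthritic arrays lay in clusters on their own side of the division between batch A and the rest, but 16 did after quantile normalization, and 10 with the largest number of probe sets or complete linkage, which gave clusters of 17 and 1. Among the 18, replicates 1 and 13 lie on their own side by construction, as each is a cluster alone. Among named genes, the matrix protein Mfap4 was lower in batch A than in the other arrays by -3.08 in arthritic and -2.61 in non-arthritic mice, and the proteoglycan Dcn by -1.31 and -1.09. The eosinophil granule gene Prg2 was higher by 2.48 and 1.08, and the marginal zone lectin Cd209b by 1.21 and 1.89. Pancreas genes were also higher in batch A, Cela3b by 1.46 and 2.94 and Zg16 by 1.09 and 3.08, and the 3 spleens with pancreas transcripts (arthritic replicate 8, non-arthritic 5 and 6) all lie in it. The Gapdh 3 prime to 5 prime ratio, a sign of RNA quality, was 0.751 ± 0.059 (SD, n = 13) in A, 1.004 ± 0.091 (n = 16) in B and 0.911 ± 0.061 (n = 7) in C. With group as a term, 12997 probe sets (48.1%) differed between the 3 batches in limma.

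Across probe sets, the difference between batch A and the rest correlated between the arthritic and the non-arthritic arrays at Pearson r = 0.625, across genes that are not independent replicates. For batch A against the rest, 8010 probe sets passed in arthritic and 7194 in non-arthritic arrays. Of those that passed in both groups 3753 of 3764 had the same direction, where 2132 shared ones are expected of independent lists. The labels give no batch, and the number of 3 clusters was set after the first expression component had been seen. The silhouette of the control probes was higher for 2 clusters (0.505) than for 3 (0.308), and the clusters of 2 give a count of 16 probe sets between the groups when used as a block.

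**Figure D3:**
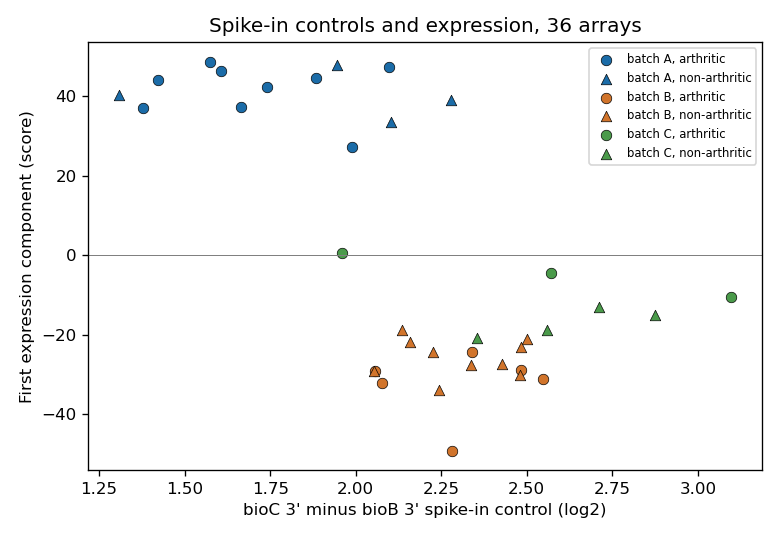
Log2 difference of 2 hybridisation control transcripts on the horizontal axis against the score on the first expression component on the vertical axis, for 36 arrays coloured by spike-in batch. Circles are arthritic and triangles non-arthritic mice. The first component holds 19.9% of the variance, and 14 arrays lie on its smaller side, among them the 13 of batch A.

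Spread between mice was compared because a mixture of subpopulations in 1 group would widen it. Red pulp macrophage scores deviated from the group median by 0.45 on average in arthritic and 0.20 in non-arthritic mice (permutation p = 0.00381, adjusted p = 0.103), and interferon scores by 0.34 and 0.16 (adjusted p = 0.116). Granulocyte precursor scores went the other way, with 0.32 and 0.58 (adjusted p = 0.116). So did acute phase and complement scores, with 0.17 and 0.31 (permutation p = 0.0107, adjusted p = 0.116, and p = 0.0202 with spike-in batch taken out). With spike-in batch taken out the macrophage difference had a permutation p of 0.38 and the interferon difference 0.341, while the granulocyte precursor difference had 0.00265 (adjusted p = 0.0716, the lowest of the 27 lists). Neutrophil scores, which deviated by 0.43 in arthritic and 0.61 in non-arthritic mice, then had a p of 0.0095, and interleukin 1 family scores 0.00817 (both adjusted p = 0.0855). Of the 27 lists 0 passed, with or without batch. Per probe set, limma on absolute deviations called 0 of 27022, with 2071 at an unadjusted p under 0.05, and 14 without the trend in the variance prior.

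The last comparison asked how list scores varied together, over 28 pairs of 8 lists in each group. Erythroid and cell cycle scores moved together across mice, with Pearson r = 0.975 and Spearman rho = 0.965 in arthritic and r = 0.936 and rho = 0.891 in non-arthritic mice (each permutation p = 1e-05, the smallest possible, adjusted p = 9.33e-05 and 0.00028). Without the 2 most distant arrays r was 0.951 and 0.881, and within batches it was 0.921 among the arthritic arrays of A, 0.989 among those of B and 0.746 among the non-arthritic arrays of B. B cell scores ran against erythroid scores, with r = -0.837 and rho = -0.837 in arthritic mice (permutation p = 2e-05 and 4e-05, adjusted p = 0.000112 for r) and r = -0.662 and rho = -0.622 in non-arthritic mice (p = 0.00249 and 0.00696, adjusted p = 0.0139). Without the 2 most distant arrays these r were -0.807 and -0.536, and within batches -0.877 (arthritic, A), -0.943 (arthritic, B) and -0.297 (non-arthritic, B).

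B cell and red pulp macrophage scores were related differently in the groups, with r = -0.846 (rho = -0.837, permutation p = 2e-05 and 5e-05, adjusted p = 0.000112) in arthritic and r = 0.42 (rho = 0.513, p = 0.0827 and 0.0313, adjusted p = 0.167) in non-arthritic mice. The difference of r, -1.26, had a permutation p of 0.00023 and an adjusted p of 0.00644 over the 28 pairs. Without the 2 most distant arrays r was -0.798 and 0.29. Within batches r was -0.615 among the 9 arthritic arrays of A, -0.653 among the 6 of B and 0.32 among the 10 non-arthritic arrays of B. With batch taken out it was -0.653 in arthritic and 0.006 in non-arthritic mice, and no difference of r passed (lowest adjusted p = 0.643 over the 28 pairs). In all 25 relations passed within the groups, and 14 without the 2 arrays farthest from the median.

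**Figure D4:**
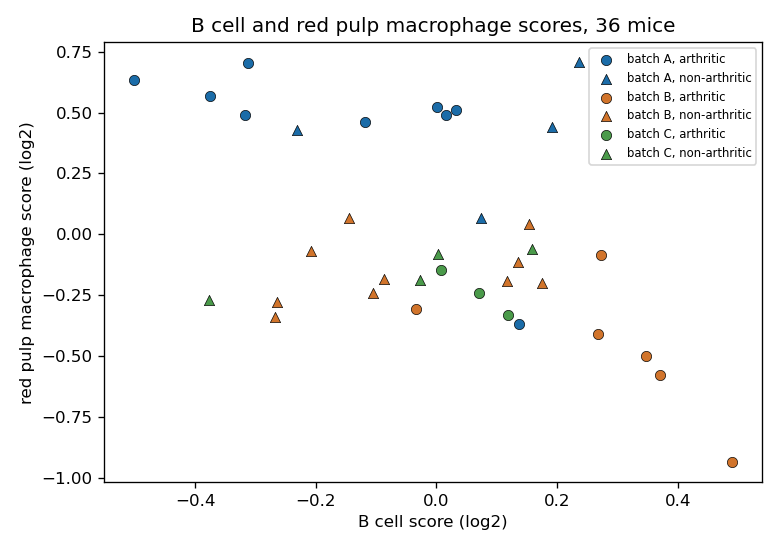
B cell score against red pulp macrophage score, both on the log2 scale, 1 point per mouse, coloured by spike-in batch, with circles for arthritic and triangles for non-arthritic mice. The pooled r of -0.846 in arthritic mice spans batches, and within A and B it was -0.615 and -0.653.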

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

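In this part the tests on spike-in batches and the split counts past the threshold over all 36 arrays were chosen after the results had been seen. The bounds of the splits that keep each batch uneven without a block, of the split counts within single batches and at unadjusted p, and of the actin test within batch B were set before the splits or fits were run, with the real counts of the unblocked and unadjusted splits already known.

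The correlation of B cell with red pulp macrophage scores differed between the groups, with a difference of r of -1.265 (arthritic minus non-arthritic, adjusted p = 0.00644 over 28 pairs), while with spike-in batch taken out no difference of r passed (lowest adjusted p = 0.643). A signal also appeared in control probe sets that the gene comparisons leave out: for 35 of 36 arrays the nearest array in spike-in profile lay on the same side of the first expression component.

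The first pattern is the 13 probe sets that rose in arthritic spleens, among them Ptpn22, Il12a and Plxnc1. Of 100 splits of the 36 arrays, 2 gave as many as the real one, itself included, and the highest other gave 21. These splits take no account of batch, and the one with 21 puts 10 of the 13 arrays of batch A in 1 group, against 9 in the real one. Of 100 splits that keep the number of arthritic arrays in each batch, 1 (the real one) gave as many without a block, with 2 in the highest other. Chance is thus unlikely to give the unblocked count in this sense, though 100 splits set no finer bound. The count also fell to 0 when any 1 of 24 arrays was left out. It was 36, 389, 250 and 20 without non-arthritic replicate 1, 2, 5 or 6, all of batch A, whose loss makes the batches more uneven. Without any 1 of the 14 other non-arthritic arrays it was 0. Without single arthritic arrays it was 0 to 3 for batch A and 0 to 48 for B and C. The size of the count thus tended to rise with the unevenness of the batches, though arthritic replicates 14, 15, 16 and 18 gave 0 or 1. For the differences of these 13 probe sets, uneven batches (9 arthritic but 4 non-arthritic arrays in A) are unlikely to be the whole cause. Their differences with batch as a block were a median of 0.86 of those without it, and each was at least 4.4 standard errors. Ptpn22 went from 0.44 (SE 0.09) to 0.43 (SE 0.09) and Plxnc1 from 0.72 (SE 0.13) to 0.55 (SE 0.10). These values cover only probe sets picked by their unblocked difference and do not account for the count. The call still ended under the block, with adjusted p between 0.0645 and 0.112 and 3221 probe sets at an unadjusted p under 0.05 against 4250. For Snx5 the unadjusted p was 8.46e-06 without and 7.16e-06 with the block, so its call ended in the adjustment over all probe sets, and for the others the share of smaller differences was not tested. With 0 probe sets 100 of 100 splits within batches must give as many (18 in the highest other), which decides nothing. At an unadjusted p under 0.05, 3 of 100 splits within batches gave as many as the real 3221 under the block, itself included, with 4835 in the highest other. Chance is thus unlikely but not excluded for that count, which names no single probe set. What stays open is arthritis itself, untested against anything that goes with it, and RNA quality. The Gapdh 3 prime to 5 prime ratio was 0.854 ± 0.143 (SD, n = 18) in arthritic and 0.934 ± 0.12 in non-arthritic arrays. With it as a covariate limma called 2 probe sets (1 higher, 1 lower), with 2979 at an unadjusted p under 0.05. The selection of these probe sets for their unblocked difference, which favours large values, stays open too.

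Within batch B, 738 probe sets differed between 6 arthritic and 10 non-arthritic arrays, and 1 of 100 splits of those arrays (the real one) gave as many, with 2 in the highest other. In batches A and C the limma counts were 0, so 100 of 100 and 35 of 35 splits must give as many, which decides nothing, and the highest other splits gave 1688 in A and 63 in C. At an unadjusted p under 0.05, 9 of 100 splits gave as many as the real 3129 in A (highest other 7250) and 21 of 35 as many as the real 1000 in C (2540), so chance cannot be excluded there. A split of A with that many probe sets may point to a structure among its arrays, which was not examined. RNA degradation cannot be told apart from arthritis in B, since 80 of the 738 were left with the actin 3 prime to 5 prime ratio as a covariate, between the written bounds, and arthritic replicate 14 has the highest ratio, 2.74. Leaving out arthritic replicate 14, 15, 16 or 18 left 4, 5, 3 and 0, while leaving out arthritic replicate 10 or 17 gave 1174 and 2200, and single non-arthritic arrays 275 to 956. The count thus depends on single arthritic arrays, in both directions. For spread per probe set, with 0 called by limma, 100 of 100 splits must give as many (4 in the highest other). At an unadjusted p under 0.05, 1 of 100 splits, the real one, gave as many as 2071 (highest other 1592). Those splits take no account of batch. With the batch effect removed the real count was 953, below the median of 1006 in the other splits, which were run without removing batch. The excess of 2071 was thus not seen once batch was removed.

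The second pattern is that arthritic replicates 1 to 9 stand apart from 10 to 18. A processing batch is a candidate cause: 35 of 36 arrays had their nearest neighbour in spike-in profile on their own side of the first component, where permutations gave 18.4 on average and 33 at most (p = 1e-05, the smallest they can give). A division found in arthritic mice alone is argued against by the correlation of 0.625 between the batch differences of the 2 groups across probe sets. That correlation does not test whether arthritic mice hold a further difference along the same division. Past the threshold were 8010 probe sets in arthritic and 7194 in non-arthritic arrays, and 3764 in both. Whether it arose in labelling and hybridisation of single probes cannot be told apart from earlier steps, because called probe sets of 1 gene moved in opposite directions in 47.8% of genes, against 57.6% with directions shuffled. A difference between mice housed or killed together that share a processing batch stays open, as does any biological subpopulation inside a batch.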

How the results depend on the processing

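Settings on spike-in batches, actin, left-out pancreas arrays, batch B and high and low sets were chosen after the data were seen; the others were planned. For all but the changes of construction named, the cause was not tested. Against 13 probe sets, limma gave 0 with no filter (5132 at an unadjusted p under 0.05, more probe sets tested), 21 (17 higher, 4 lower) with the filter at the 60th percentile (fewer tested), 1 after quantile normalization, 0 without the trend (4177), 1 without outlying arrays or without arrays of high actin ratio (both arthritic replicate 14), 2 with the Gapdh ratio, 37 with the actin ratio, 220 with the pancreas score and 2322 (1362 higher) with Xist as a covariate, and 236 without the 3 arrays with pancreas transcripts; the Wilcoxon test gave 0 (4155). The 3 arrays with pancreas transcripts (arthritic replicate 8, non-arthritic 5 and 6) all lie in batch A, so leaving them out makes that batch more uneven. Leaving out non-arthritic replicate 5 alone gave 250, so the 236 cannot be laid to pancreas transcripts. Pseudocounts of 1 and 64 gave 13 and 14, robust eBayes 15 and 1 probe set per gene 11. Spike-in batch as a block gave 0 (3221), with quantile normalization 1, without high actin ratio 0 (2656); Ward linkage with 2, 4 and 5 clusters gave 16, 0 (3407) and 0 (3361), average linkage with 3, 4 and 5 clusters 7, 1 and 0 (3361), and 2 principal components of the controls 4. Within batches A, B and C the counts were 0 (3129), 738 and 0 (1000), with 80 in B with the actin ratio and 0 to 2200 in B leaving out 1 array in turn. Replicate number as a block gave 369 probe sets (271 higher) and 1 gene list, the interleukin 1 family (adjusted p = 0.0329). The labels state no link between mice of the same number. Of 18 pairs 11, and not all, correlated above 0.1 (median 0.151, from -0.228 to 0.473), and 2 arthritic and 4 non-arthritic arrays correlated best with their own number. Mice numbered 1, 2, 5, 6, 11, 12 and 14 to 18 share a spike-in batch with the same number in the other group. The replicate block thus also carries batch, and whether that accounts for the pair correlations was not tested. Leaving out each of the 36 arrays gave 0 to 389: 389 and 250 without non-arthritic replicates 2 and 5, 36 and 20 without 1 and 6, and 48, 38, 37, 31 and 19 without arthritic 11, 13, 17, 10 and 12, 3 without arthritic 1, 1 without arthritic 14 or 16, and 0 without each of the other 24 (10 arthritic, 14 non-arthritic). The spread test gave 14 without the trend and 0 in the other settings, each array left out included. Lists past the threshold were 1 with the batch block, 9 with camera at the preset correlation, 0 at the estimated one, and 1 with fry; the correlation of list scores gave 14 relations without the 2 arrays farthest from the median, 26 with list medians and 24 with batch taken out. Separation of whole profiles by group passed in all 5 alternatives (pseudo-F 1.65 to 2.19). No clustering of arthritic arrays passed (lowest p 0.123), in a test that cannot argue against subpopulations. The difference in distance to the centroid turned to 0.0105 with the largest number of probe sets and 0.398 with Euclidean distance, p above 0.5 in both. High and low sets of mice were found for 16 genes with pseudocount 1, 11 with 64 and 15 after quantile normalization, which held 14, 10 and 12 of the 15 genes. Of 56 named genes, signs turned within batch A for Ermap (0.197), Alas2 (0.143), Fcrl1 (-0.0961), Ccna2 (0.371), Mcm4 (0.281), Casp1 (-0.13), Kdm5d (-0.198) and Uty (-0.228), within batch C for Herpud1 (-0.0208), Eif2s3y (-0.062), Uty (-0.139), H2-Eb1 (-1.264) and Il1rn (0.3004), and for Il1rn without arthritic 14 (0.0144), with Xist (0.0948), without the pancreas arrays (0.0782) and over left-out arrays (-0.106 to 0.0536). Signal over background limits dim probe sets, and a pixel-level check was not run.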

Other observations

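The test of neighbouring genes below was set, with its bounds, before its result was seen, and the tests of group frequency were chosen after the high and low sets had been seen.

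Some genes split the 36 mice into a high and a low set, whatever the group. Mndal, an interferon-inducible gene, was at 12.69 ± 0.35 (SD) on the log2 scale in 26 mice and 7.83 ± 0.63 in 10. Adamdec1, a macrophage metalloprotease, was at 10.73 in 27 mice and 6.17 in 9, and Gbp2b, a guanylate-binding protein, at 9.22 in 26 and 6.21 in 10. The class II genes H2-Ea and H2-Eb1 were at 14.15 and 14.05 in 26 mice and at 10.91 and 11.11 in 10, and Ctps2 at 9.71 in 23 and 7.33 in 13. In all, 15 of 12417 genes had at least 85% of their variance between sets and a gap of at least 1.5 log2. High mice were 17 of 18 arthritic and 10 of 18 non-arthritic for Adamdec1 (Fisher's exact test p = 0.0178, adjusted p = 0.266 over 15 genes), 16 and 10 for Gbp2b (adjusted p = 0.3) and 15 and 11 for H2-Eb1 (adjusted p = 0.661), so 0 of the 15 passed, with 1 at an unadjusted p under 0.05.

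These sets may reflect alleles that segregate in the F2 cross. Pairs of these genes with different name stems that lie within 100 genes of each other on a chromosome had a median absolute r of 0.956 across mice, against 0.303 at the 95th percentile of 1000 shuffles of positions (p = 0.003). There were 3 such pairs from a pair of places: H2-Ea and H2-Eb1 with Msh5 (r = 0.958 and 0.956), and Mrap2 with Zfp949 (r = 0.94). The spike-in batches took a median of 9.7% of the variance of the 15 genes, which argues against batch as their common cause, with the exception of Mfap4 at 80.8%. A sequence variant under a probe would give the same sets and stays open, as no strain sequences were used here.

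Pancreas transcripts, such as Cel and Zg16, stood out in 3 spleens, with an acinar score of 4.88 in arthritic replicate 8, 5.47 in non-arthritic replicate 5 and 4.03 in non-arthritic replicate 6, and 0.33 in the next mouse. Of the 19 acinar genes listed 6 passed the filter on low values.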
